A study of Mus musculus with 8 samples.

How the data were processed

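Per the labels, mice of strain C57BL/6 were treated on the ears with MC903, a vitamin D analogue that brings on a dermatitis used as a model of atopic dermatitis. On day 10, CD4+ T cells were sorted by flow cytometry from the lesional skin, and their RNA was captured with the droplet-based 10x Genomics 3' chemistry (v3). The 8 libraries form 8 groups with 1 library each: lean; obese; lean Cre control (CD4-Cre); lean PPARg TKO (CD4-Cre PPARg fl/fl, a T cell knockout of the nuclear receptor PPARγ); and 4 libraries from obese mice, WT or PPARg TKO, given either a control high-fat diet or a high-fat diet with rosiglitazone, a PPARγ agonist. The labels assign the first 4 libraries and the last 4 to different main figures of the study. The number of mice pooled per library, the dose of the drug and the date of each library are not given in the sources used here.

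Per the labels, the authors aligned reads to mm10 with Cell Ranger, whose version is not stated. The deposited matrices hold raw UMI counts per gene and cell barcode, with barcodes already called as cells, and the values were checked to be whole numbers of at least 1 over 31053 genes. In the order lean, obese, lean Cre control, lean TKO, WT control, TKO control, WT rosiglitazone and TKO rosiglitazone (the last 4 obese), the deposited UMI counts total 14195500, 18906360, 12331007, 11373778, 30921735, 20595077, 26529696 and 21199689. Gene positions are those of mm10 with the GENCODE vM21 annotation, matched by gene identifier; the annotation release the authors used is not given in the sources used here.

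Barcodes were kept with at least 500 detected genes and at most 10% mitochondrial UMIs, which left 24088 of 28464. Scrublet, run within each library through scanpy 1.11.5, called 13 of 26471 scored barcodes doublets (0.0491%); so low a share means that the tool has not worked on these libraries, and doublets remain in the data. The 12 calls among barcodes passing the filter were removed. All kept barcodes were clustered together: UMIs were scaled to 10000 per cell and log-transformed, 2000 variable genes were chosen within libraries, and Leiden communities (leidenalg 0.10.2, resolution 1) were found on a graph of 15 neighbours (scikit-learn 1.9.0) in 30 principal components. The type 1, type 2 and type 17 helper lists, the PPARγ list, T cell receptor, immunoglobulin and mitochondrial genes were left out of the variable genes, so that the genes under comparison did not shape the clusters. No batch correction was applied, because library set and group coincide. A cluster was taken as another cell type when at least 3 of its 10 leading genes belonged to lists of other cell types; 4 of the 17 clusters, with 483 cells, were left out on this ground, and 23593 T cells remained. Clusters were named after a T cell list other than the alpha-beta list, and lists of other cell types were not weighed in the naming. The name was that of the list with most markers at least 1.5-fold higher than in other cells. It needed at least 3 such markers at 10 CPM or more, and more of the leading genes than any other of these T cell lists. Failing that, at least 8 such markers sufficed where no other of these T cell lists had a leading gene. This naming rule was set after the clusters had been seen; clusters 0, 3, 6 and 13 received no name under it.

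UMIs were summed over the T cells of each library and expressed as CPM, the count scaled to a common library total. Each of 6 comparisons of 2 libraries was described by log2 ratios of CPM with a pseudocount of 1, and by the fold with an exact interval conditional on the summed UMIs. With 1 library per group there is no replicate, so no test between groups was made and no number of changed genes is given. All intervals are 95% intervals and cover counting error only: exact Poisson for CPM, Clopper-Pearson for shares of cells, Newcombe for differences between shares. Those for CPM and folds treat UMIs as independent, so they are too narrow for genes whose UMIs lie in few cells. A count of 0 was read as an upper limit of 3 counts. The share of T cells with at least 1 UMI of a cytokine set (type 2, Il4, Il5 or Il13; type 17, Il17a, Il17f or Il22) was taken after each cell was thinned at random to 2000 UMIs, leaving out shallower cells. The same share in regulatory T cell-like clusters, which should make little of either set, stands beside it as background.

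Of 35 gene lists, 22 had at least 3 members with a mean of at least 5 CPM, and their median log2 ratio is given with its percentile among 10000 random lists of the same size matched on expression, as a description of the libraries compared. The other lists, mostly markers of other cell types, are given as summed CPM. A member was counted as higher or lower past 1.5-fold. Named genes follow a rule: the 10 highest and 10 lowest log2 ratios among genes with a mean of at least 20 CPM in the 2 libraries, leaving out mitochondrial, ribosomal protein, hemoglobin, antigen receptor, keratin-type and sex-linked control genes, unnamed gene models and markers of other cell types; always Pparg, Il4, Il5, Il13, Il17a, Il17f, Il22, Ifng, Gata3, Tbx21 and Foxp3; and up to 4 members of each list with the largest ratios. Some genes that the rule selects are not reported. The lists, the comparisons, the cell filter, the gene rule and most alternatives were fixed before the data were examined. The same statistics are given for 2 contrasts between libraries with no difference in diet or drug, lean Cre control against lean and obese WT control HFD against obese, which the labels do not call replicates.

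The statistics were tested on simulated data drawn from the obese and lean libraries. Counts were drawn at random around a pooled profile of both, so counting error was simulated but the spread between libraries was not. The rates below therefore do not carry over to differences between real libraries. Among 5294 genes, 200 were given a 2-fold change; 100% of these and 0% of the others passed 1.5-fold, a changed list of 15 genes lay at percentile 100, and 7% of 100 unchanged lists fell outside the central 95%. The intervals covered the true value in 95.3% (Poisson), 96.6% (fold) and 95.7% (Newcombe) of draws. The alternatives tried were thinning to 4000 UMIs or none, a filter of 1000 genes and 5% mitochondrial UMIs, doublet calls kept, T cells chosen by their own UMIs, proliferating cells or regulatory T cell-like clusters left out, median-of-ratios size factors, the mean over cells of each cell's CPM, no minimum CPM, a pseudocount of 5 CPM, a clustering resolution of 0.5 and a clustering that kept the helper lists. Chosen after seeing the data were leaving out clusters 0 and 7, a limit of 20% mitochondrial UMIs, removing the highest doublet scores at 0.8% per 1000 barcodes, and clustering cells thinned to 2000 UMIs. Computations used Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3, and figures matplotlib 3.10.9.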

Results

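The series asks whether obesity shifts the helper programme of CD4+ T cells in inflamed skin, and whether PPARγ in T cells, or its agonist rosiglitazone, bears on that shift. Short names are used for the 8 libraries: lean, obese, lean Cre control (CD4-Cre), lean TKO (CD4-Cre PPARg fl/fl), and, all from obese mice on a high-fat diet, WT control, TKO control, WT rosiglitazone and TKO rosiglitazone. Values for all libraries are given in that order. Each group is a single library, so every difference below lacks a replicate check, and square brackets hold 95% intervals that cover counting error only. T cells kept numbered 2265, 3380, 1564, 1951, 5024, 2864, 3105 and 3440, with median UMIs of 4447, 3732, 5000, 4262, 3887.5, 4755, 4465 and 4168.5. The cell filter removed 18.5%, 25.3%, 35.5% and 27.9% of barcodes in the first 4 libraries and 6.79%, 5.25%, 10.9% and 3.50% in the last 4.

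The sorted cells were a mix of regulatory and helper T cells. Regulatory T cell-like clusters, with leading genes such as Lrrc32, which presents latent TGFβ, and Il10, held 54.1%, 48.9%, 63.4%, 53.5%, 36.0%, 32.2%, 32.7% and 32.4% of T cells. The type 17-like cluster, led by Il17f, Pxdc1, Ramp1 and Il22, held 10.4%, 10.1%, 8.18%, 8.71%, 7.54%, 15.5%, 7.41% and 10.9%. The type 1-like cluster, led by the chemokine gene Ccl5 and by Ly6c2, held 7.68%, 14.5%, 3.39%, 7.94%, 3.01%, 2.03%, 6.02% and 1.48%. Proliferating cells, led by Birc5 and Cdca3, held 4.64%, 3.40%, 4.41%, 3.38%, 13.7%, 10.5%, 9.82% and 12.1%, and naive-like cells, led by Igfbp4 and Lef1, 0.662%, 0.621%, 0.831%, 1.08%, 0.219%, 0.105%, 0.548% and 0.116%. Of the unnamed clusters, cluster 0 (Il17a, Zeb1) held 5.12%, 4.79%, 5.63%, 1.79%, 20.4%, 25.5%, 20.5% and 28.8%, cluster 3 (Ccl1, Csf2, Il13) 8.79%, 8.20%, 8.38%, 11.8%, 10.5%, 9.32%, 13.7% and 9.59%, cluster 6 (Myo6, Pdlim4, Il4) 7.77%, 8.14%, 5.56%, 10.9%, 8.12%, 4.68%, 8.79% and 4.42%, and cluster 13 (Ifit3, Ifit1) 0.883%, 1.33%, 0.192%, 0.923%, 0.418%, 0.279%, 0.548% and 0.203%. Cluster 0 and the proliferating cluster 7 came mostly from the last 4 libraries. They held Foxp3 at 353 and 225 CPM and Ikzf2 at 1099 and 853 CPM. The regulatory T cell-like shares thus leave out Foxp3-bearing barcodes, mostly in the last 4 libraries, and shares outside those clusters include them. After thinning to 2000 UMIs, a Foxp3 UMI was found in 31.0% to 43.1% of T cells in the first 4 libraries and 31.9% to 35.7% in the last 4. Cluster 8 (Cxcr4, Malat1, Fosb), counted in the regulatory T cell-like class, came mostly from the first 4, with 397 lean Cre control but 20 TKO rosiglitazone cells. It was shallow (median 1446 UMIs) and had a median of 7.63% mitochondrial UMIs. Its Il22 was 44.9 CPM, the highest of that class, so it may add to the background shares below. Cluster sizes are not read as differences between groups, because leading genes of several clusters, Pxdc1 and Itga4 among them, differ between libraries themselves.

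After thinning to 2000 UMIs, which left out 237, 423, 275, 313, 1250, 253, 465 and 490 T cells, a type 17 cytokine UMI (Il17a, Il17f or Il22) was found in 2.66%, 4.67%, 4.97%, 6.29%, 2.94%, 18.0%, 5.04% and 12.7% of T cells. Without thinning the shares were 3.75%, 6.07%, 6.65%, 7.48%, 4.72%, 24.4%, 8.24% and 17.8%. In regulatory T cell-like clusters, whose cells should make little of these cytokines, the thinned share was 1.37%, 1.57%, 1.94%, 3.06%, 2.22%, 3.64%, 2.65% and 3.63%, at median UMIs of 3748, 3198.5, 3705, 3281.5, 2145, 3008, 2603 and 2746. A type 2 cytokine UMI (Il4, Il5 or Il13) was found in 6.71%, 5.38%, 7.45%, 6.11%, 6.70%, 4.63%, 8.67% and 6.203% of thinned T cells, in 10.6%, 9.82%, 13.5%, 10.0%, 10.9%, 8.48%, 16.9% and 9.85% of T cells without thinning, and in 0.783%, 0.749%, 1.94%, 1.07%, 0.403%, 0.540%, 0.697% and 0.907% of regulatory T cell-like cells.

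**Figure D1:**
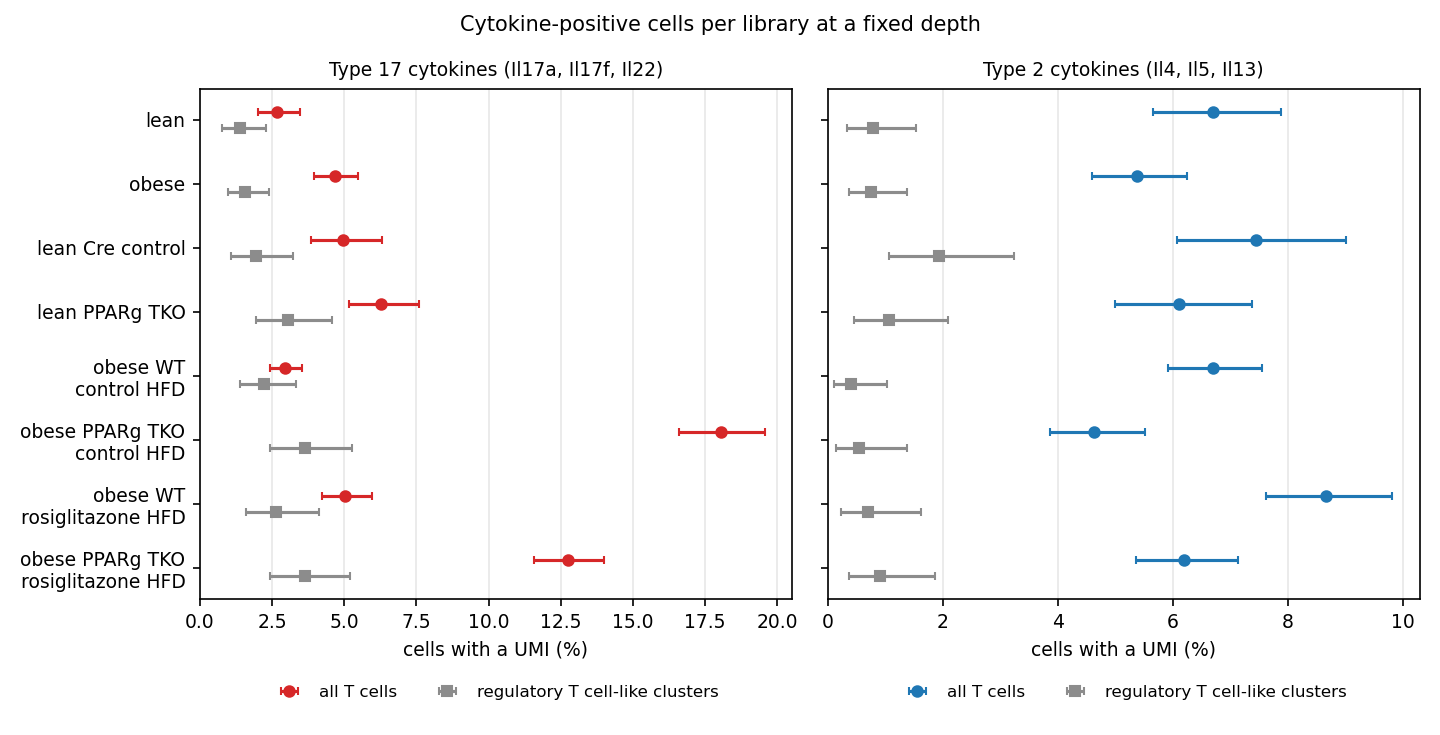
Share of T cells (%) with a type 17 (left) or type 2 (right) cytokine UMI after thinning to 2000 UMIs, in all T cells and in regulatory T cell-like clusters of each library, with 95% intervals for counting error. The type 17 share was 18.0% in TKO control and 2.94% in WT control.

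Pparg, the targeted gene, encodes the lipid-sensing nuclear receptor that binds rosiglitazone. It lies on chromosome 6 at 115360951 to 115490399 (mm10, GENCODE vM21) and was scarce in every library: 40, 32, 38, 13, 104, 62, 88 and 59 UMIs, or 3.04 [2.17 to 4.14], 1.91 [1.31 to 2.70], 3.82 [2.70 to 5.24], 1.29 [0.686 to 2.20], 3.60 [2.94 to 4.36], 3.26 [2.502 to 4.18], 3.66 [2.94 to 4.51] and 3.02 [2.30 to 3.89] CPM. In lean TKO it stood at 0.337-fold [0.165 to 0.648] of lean Cre control, but in TKO control at 0.907-fold [0.651 to 1.25] of WT control and in TKO rosiglitazone at 0.824-fold [0.582 to 1.16] of WT rosiglitazone. These tags come from the 3' end of the transcript, and which part of the gene is deleted is not given in the sources used here. Tags outside the deleted part would still be counted, so the Pparg values check neither the presence nor the completeness of the deletion.

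**Figure D2:**
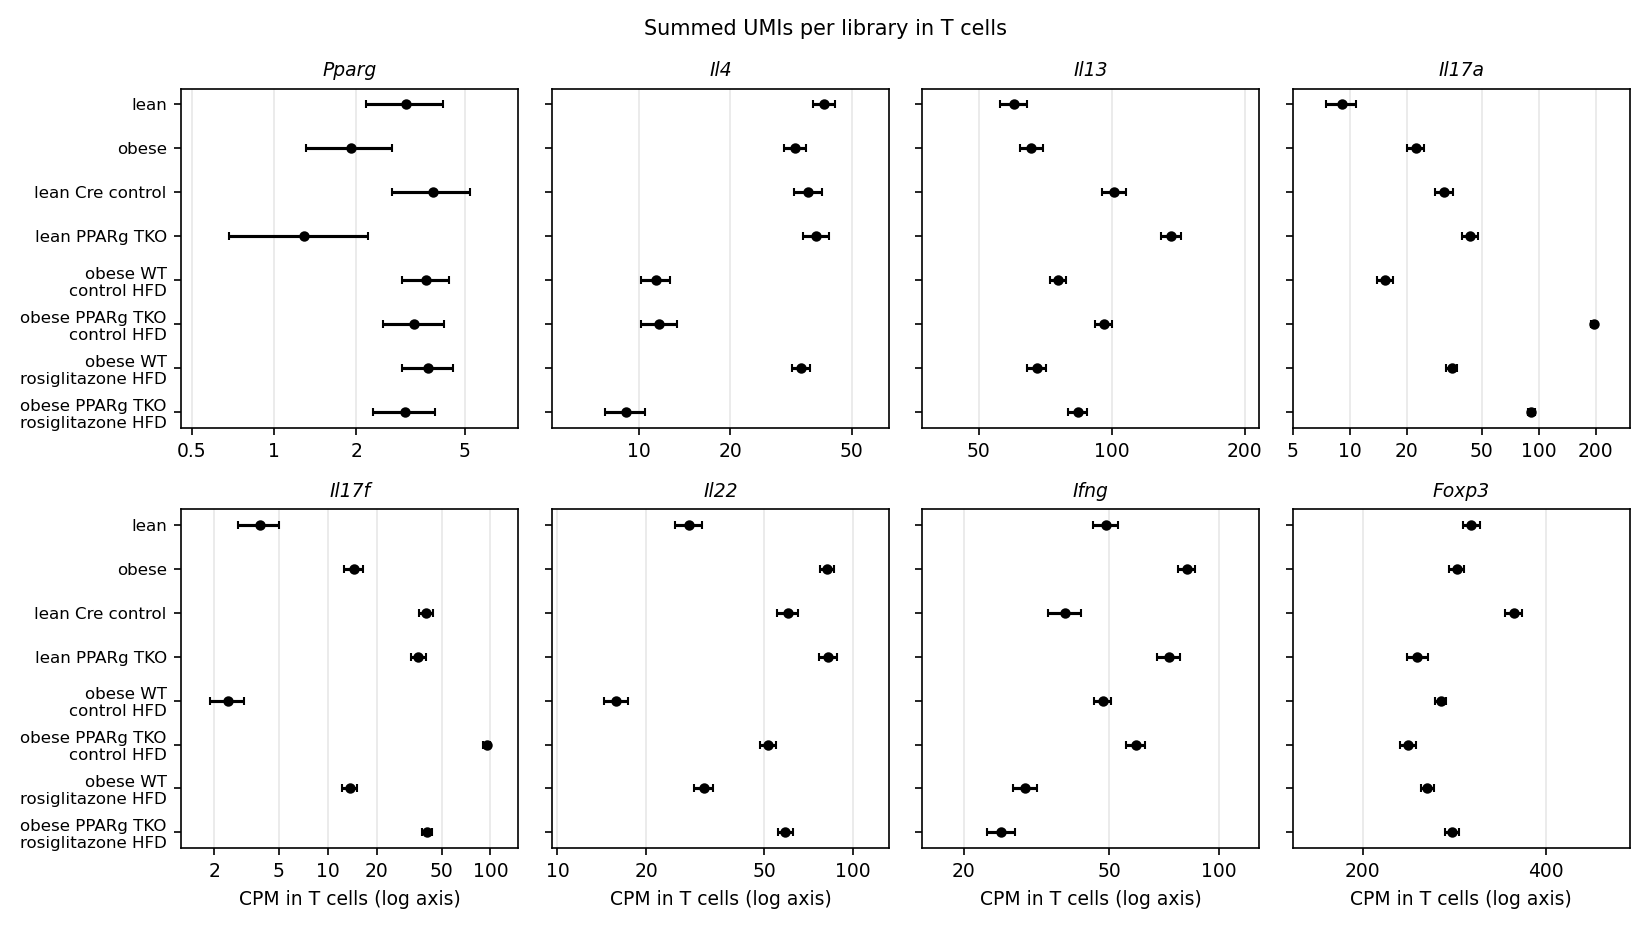
Expression (CPM, log axis) of Pparg, Il4, Il13, Il17a, Il17f, Il22, Ifng and Foxp3 in the T cells of each library, with 95% Poisson intervals. Il17a was 195 CPM in TKO control and 15.4 CPM in WT control.

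How far apart do libraries lie when neither diet nor drug differs? Lean Cre control and lean differed most in cytokine genes of the type 17 programme. Il17f was 10.5-fold [7.84 to 14.4] higher in lean Cre control, Il17a 3.50-fold [2.82 to 4.36] and Il22, an epithelium-acting cytokine, 2.16-fold [1.90 to 2.47], with a type 17 list median of 0.23. The 10 highest cells held 71.4% of Il17f, 54.9% of Il17a and 80.6% of Il22 UMIs in lean Cre control. In lean they held 90%, 63.9% and 74.8%. A single lean Cre control cell held 122 of 399 Il17f UMIs, so the folds may lie outside the intervals given. In lean Cre control the type 17 share was 2.30 points [0.979 to 3.76] higher. Type 1 and interferon genes were lower, with list medians of −0.31 and −0.36. WT control against obese showed the other direction for type 17 genes: Il17f was at 0.168-fold, Il22 at 0.193-fold and Il17a at 0.687-fold, with a list median of −0.71 and a share 1.73 points lower. Il4 was at 0.348-fold and Ifng at 0.589-fold of obese, the interferon median was −0.74 and the proliferation median 0.92, with 11 of 14 members higher. These contrasts cross the presence of Cre or the library set, and show how large a difference can arise outside the comparisons of interest.

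The comparison of obese with lean asks which helper programme differs with diet. Cytokine genes of the type 17 programme, which drives neutrophil-rich barrier inflammation, were higher in obese, along with some interferon-inducible genes and summed Ifng UMIs. The type 2 list, typical of atopic dermatitis, had a median near 0. Cell-cycle and sterol synthesis genes were somewhat lower in obese, and so were the immediate early genes Fos and Fosb. Il22 was 81.6 CPM in obese and 27.8 in lean (2.94-fold [2.62 to 3.31]), Il17f 14.4 and 3.80 (3.79-fold [2.78 to 5.25]), and Il17a 22.4 and 9.05 (2.48-fold [2.01 to 3.07]). The 10 highest cells held 66.8% of Il22 UMIs in obese and 74.8% in lean. Among 12 measured type 17 genes, only Il17f, Il22 and Il17a were past 1.5-fold, and Tmem176a (1.43-fold) and Tmem176b (1.27-fold) were between; the median was 0.36, at percentile 100. A type 17 cytokine UMI was found in 4.67% [3.93 to 5.49] of obese and 2.66% [2.01 to 3.46] of lean cells, a difference of 2.00 points [0.943 to 3.03].

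Type 1 genes had a median of 0.29 (percentile 100), with Ifng at 81.5 and 48.9 CPM (1.67-fold [1.52 to 1.83]), Ccl5 at 242 and 158, and Xcl1 also higher in obese, whereas Tbx21, which encodes T-bet, was at 12.9 and 13.8. The share of cells with an Ifng UMI differed by 0.646 points [−0.630 to 1.87], an interval that includes 0, and in obese the 10 highest cells held 42.2% of Ifng UMIs. Interferon response genes had a median of 0.17 (percentile 100): the guanylate-binding protein gene Gbp2 (53.2 and 30.9 CPM), Iigp1 (33.1 and 19.6) and Ifi47 (87.3 and 57.0) were past 1.5-fold and 12 others were not, and Gbp5 was 1.73-fold higher. In the type 2 list the median was −0.04, and all 9 measured members were within 1.5-fold. Il13, which acts on keratinocytes, was 65.9 and 60.1 CPM (1.096-fold [0.9996 to 1.203]), Il4 was 32.6 and 40.6 (0.804-fold [0.712 to 0.907]) and Gata3 351 and 362, while Il5, the eosinophil factor, was low, with 63 UMIs in obese and 17 in lean (2.91-fold [1.68 to 5.31]), each from 10 cells. The type 2 share differed by −1.33 points [−2.72 to 0.00469] while summed type 2 cytokine CPM were 102.3 and 102.0, so no order is read. Outside regulatory T cell-like clusters the share was 9.19% [7.83 to 10.7] in obese and 12.7% [10.7 to 14.9] in lean, −3.53 points [−6.09 to −1.09].

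Foxp3, the regulatory T cell regulator, was 285 CPM in obese and 302 in lean, and the share of cells with a Foxp3 UMI was 33.1% and 36.8%, a difference of −3.64 points [−6.35 to −0.952]. The other genes farthest apart were Sgip1 (1.76-fold), Ramp1, a receptor component for the neuropeptide CGRP (1.72-fold), the integrin gene Itga4 (1.72-fold), Traf4 (1.67-fold) and Myo6 (1.67-fold), all higher in obese. Lower in obese were Csf2, which encodes GM-CSF (16.1 and 36.4 CPM, 0.444-fold), Lgals7 (0.475-fold), Adam8 (0.538-fold) and Fos (398 and 643 CPM, 0.619-fold). List medians were −0.20 for proliferation, −0.25 for sterol and fatty acid synthesis, 0.12 for glycolysis and hypoxia, with the lactate transporter gene Slc16a3 1.62-fold higher, and −0.07 for immediate early and dissociation stress. They were −0.08 for T cell receptor activation, with Egr3 and Il2 lower, −0.13 for tissue residency, 0.04 for PPARγ and lipid handling, 0.03 for regulatory T cell, 0.06 for naive or central memory, −0.02 for alpha-beta T cell, −0.04 for fatty acid oxidation, −0.04 for oxidative phosphorylation, −0.05 for inhibitory receptors, 0.02 for tissue repair and alarmin response, 0.04 for cytokine receptors and STAT signalling, and 0.05 for NF-kappaB response. Lean Cre control and lean differed in type 17 share by as much, 2.30 points, and under the stricter cell filter the obese to lean difference was 0.836 points [−0.362 to 2.02], an interval that includes 0.

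Lean TKO against lean Cre control asks what differs with the T cell knockout of PPARγ in lean mice, with Cre present in both. Some type 2 receptor genes and many cell-cycle genes were lower in lean TKO, and the regulatory T cell and lipid handling lists leaned lower with 1 member each past 1.5-fold. Type 1 genes and some genes of the CD8 T cell list were higher, and type 17 genes other than Il17f leaned higher. The type 2 list had a median of −0.44 (percentile 0). Il1rl1, the receptor for the alarmin IL-33, was at 199 CPM in lean TKO and 345 in lean Cre control (0.579-fold), the IL-9 receptor gene Il9r at 23.8 and 38.4 (0.620-fold), the IL-25 receptor gene Il17rb was also past 1.5-fold, and Gata3 was at 257 and 349 (0.737-fold [0.700 to 0.775]). The cytokines were mixed: Il13 was 136.5 and 101 CPM (1.35-fold [1.24 to 1.46]) but came from 103 and 124 cells, with 63.6% and 57.1% of its UMIs in 10 of them, Il4 was 38.3 and 36.1, and Il5 was lower, read from 3 and 20 UMIs (0.148-fold [0.0282 to 0.499]). The type 2 share was 6.11% and 7.45%, against the direction of the summed CPM (175.1 and 139.5), so no order is read. Outside regulatory T cell-like clusters it was 10.4% [8.44 to 12.6] and 14.4% [11.6 to 17.6].

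Type 1 genes had a median of 0.76 (percentile 100), with 6 of 10 higher: Il12rb2, the receptor through which IL-12 acts (14.9 and 5.73 CPM), Ccl4 (30.4 and 13.6), Ifng (72.9 and 37.8, 1.93-fold [1.701 to 2.19]), Nkg7 (216 and 121), Tbx21 (13.5 and 7.54, 1.79-fold [1.34 to 2.40]) and Cxcr3. Lean Cre control was itself low beside lean, at 0.544-fold [0.410 to 0.716] for Tbx21, which was 13.8 CPM in lean, and 0.773-fold [0.678 to 0.879] for Ifng. The natural killer receptor genes Klrc1 (2.78-fold) and Klrd1 (2.58-fold), Ifitm1 (773 and 292 CPM, 2.64-fold), Ifitm3 (2.03-fold) and the chemokine Ccl1 (141 and 66.9 CPM) were among the farthest higher. The CD8 T cell list was higher too (median 1.01), with the granzyme gene Gzma at 19.8 and 6.03 CPM and Ctsw at 88.2 and 43.2, while Cd8b1 was at 10.3 and 14.1. Interferon response genes had a median of 0.26, with Ifit1 at 16.1 and 4.42 CPM, and Rtp4 and Isg15 also higher. The type 17 median was 0.53 (percentile 100), with 6 of 12 past 1.5-fold, among them Tmem176a (1.69-fold) and Serpinb1a (1.61-fold). Il17a (43.4 and 31.7 CPM, 1.37-fold [1.18 to 1.59]) and Il22 (1.37-fold) were between and Il17f was at 0.897-fold [0.776 to 1.04]. A single lean Cre control cell held 122 of the 399 Il17f UMIs of that library, so the Il17f order may rest on it. The 10 highest cells held 59.2% of Il17f UMIs in lean TKO and 71.4% in lean Cre control. For Il17a they held 59.6% and 54.9%, and for Il22 87.1% and 80.6%. The type 17 share was 6.29% [5.16 to 7.57] in lean TKO and 4.97% [3.84 to 6.30] in lean Cre control, a difference of 1.32 points [−0.384 to 2.98] that includes 0.

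Regulatory T cell genes had a median of −0.32, with Klrg1 (98.1 and 159 CPM) past 1.5-fold and Foxp3 at 246 and 354 CPM (0.695-fold [0.660 to 0.732]); a Foxp3 UMI was found in 31.0% and 43.1% of cells, −12.1 points [−15.6 to −8.59], where lean Cre control stood 6.27 points [2.85 to 9.69] above lean. Of 14 proliferation genes 7 were lower, Ccnb2 (18.8 and 36.8 CPM) and Mki67 (60.4 and 94.9) among them, and the median was −0.53. The PPARγ and lipid handling median was −0.36, with the lipid droplet gene Plin2 at 14.7 and 27.7 CPM (0.529-fold), and in fatty acid oxidation (median 0.00) Etfdh was lower (19.3 and 30.2 CPM). Rell1 (15.3 and 45.8 CPM, 0.333-fold [0.276 to 0.401]), Cenpf (0.446-fold), the proprotein convertase gene Pcsk1 (0.475-fold), Hlf (0.497-fold) and Myo6 (0.498-fold) were the farthest lower. Other medians were 0.30 for naive or central memory, with Tcf7 at 106 and 61.3 CPM, −0.31 for tissue repair and alarmin response, with Il10 at 41.9 and 69.7 and the epithelial growth factor Areg at 519 and 740, −0.22 for NF-kappaB response, −0.18 for cytokine receptors and STAT signalling, −0.12 for immediate early and dissociation stress and −0.06 for inhibitory receptors. Oxidative phosphorylation (0.09) and T cell receptor activation (−0.08) were close to no difference.

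TKO control against WT control puts the same question in obese mice. The type 17 programme as a whole was far higher in TKO control, in its cytokines and its surface genes, and in the share of cells that express it. Activation, NF-kappaB, stress and tissue residency genes were moderately higher. Median ratios of the type 2 and type 1 lists were small. Il17f was 94.6 CPM in TKO control and 2.42 in WT control (39.0-fold [30.7 to 50.3]), Il17a 195 and 15.4 (12.7-fold [11.5 to 14.03]) and Il22 51.6 and 15.8 (3.27-fold [2.92 to 3.66]). Of 12 type 17 genes 11 were higher past 1.5-fold, with Tmem176a (107 and 30.8 CPM) and Tmem176b (93.6 and 27.9) among them, and the chemokine receptor gene Ccr6 was between; the median was 1.68 (percentile 100). A type 17 cytokine UMI was found in 18.0% [16.6 to 19.6] of TKO control and 2.94% [2.43 to 3.53] of WT control cells, 15.1 points [13.6 to 16.7] apart. The 10 highest cells held 16.1% of Il17a, 10.4% of Il17f and 53.9% of Il22 UMIs in TKO control. WT control was low beside obese, where Il17f was 14.4 CPM, Il17a 22.4 and Il22 81.6. TKO control lay above obese in Il17f and Il17a but below it in Il22. Pxdc1, a leading gene of the type 17-like cluster, was 126 and 21.1 CPM (5.97-fold), and the natural killer receptor genes Klrc1 (45.8 and 8.41, 5.45-fold) and Klrk1 (114 and 39.2, 2.91-fold), Actn2 (3.15-fold) and Nmrk1 (2.70-fold) followed.

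T cell receptor activation genes had a median of 0.41, with Tnfsf11, which encodes RANKL (131 and 71.1 CPM), Tnfsf8 (435 and 238) and Nr4a1 (367 and 211) higher. NF-kappaB genes (0.39, with Tnf at 43.1 and 23.7 CPM and Birc3), stress genes (0.35, with the heat shock gene Hsph1 and Zfp36), tissue residency (0.35, with Bhlhe40 at 462 and 223 CPM and the skin-homing receptor gene Cxcr6 at 253 and 133), tissue repair (0.41, with Furin at 510 and 252 and Penk, the enkephalin precursor gene, at 260 and 131) and interferon response (0.31, with Rsad2 past 1.5-fold) were all at or above percentile 99.98. WT control had the lowest summed stress genes of all libraries, 11711 CPM against 13445 to 17535. Cytokine receptor and STAT genes had a median of 0.20. Proliferation genes were lower (−0.30, with Ccnb1 at 17.4 and 27.0 CPM), as was oxidative phosphorylation (−0.17). The farthest lower genes were Rell1 (20.4 and 42.0 CPM, 0.485-fold), Lgals7 (0.497-fold), Hist1h2ae, Ifitm3 (0.638-fold) and Ttn.

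In the type 2 list (median −0.06) Il13 was 96.0 and 75.7 CPM (1.27-fold [1.19 to 1.35]), Il5 9.74 and 4.26 (2.29-fold [1.81 to 2.90], 83.2% of the TKO control UMIs in 10 cells), Il4 11.7 and 11.4 and Gata3 271 and 292. The type 2 share was 4.63% in TKO control and 6.70% in WT control, −2.07 points [−3.19 to −0.914]. Outside regulatory T cell-like clusters it was 6.26% [5.20 to 7.45] and 8.95% [7.92 to 10.1]. This runs against the summed CPM (117.4 and 91.3), and no order is read. Type 1 genes had a median of 0.04, with Xcl1 higher and Ifng at 59.1 and 48.0 CPM, and Tbx21 was at 7.47 and 8.44. Regulatory T cell (−0.04) and naive (−0.02) medians were small, and a Foxp3 UMI was found in 32.0% and 34.5% of cells. The PPARγ and lipid handling list was close to equal (0.08), with Dgat2, which makes triglyceride, at 47.5 and 29.7 CPM. Among markers of other cell types, Kit was 17.4 and 6.23 CPM (2.80-fold [2.33 to 3.37]) and Gzma 17.9 and 30.9. Per the labels the WT mice carry no Cre, so the presence of Cre differs here beside Pparg.

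WT rosiglitazone against WT control asks what differs with the drug in obese mice without the knockout. The type 2 cytokine gene Il4 was higher with the drug, and so were the type 17 cytokines, in a larger share of cells for both sets. WT control was itself low beside obese, where Il4 was 32.6 CPM, Il17a 22.4, Il17f 14.4 and Il22 81.6. Against obese, WT rosiglitazone was close in Il4 and Il17f, lower in Il22 and higher in Il17a. The ratios to WT control may therefore rest in part on that library. Cell-cycle genes and summed Ifng UMIs were lower, and the naive or central memory list leaned higher. Genes of lipid handling differed little as a list. Il4 was 34.1 and 11.4 CPM (3.00-fold [2.64 to 3.43]), with 14.9% and 16.5% of its UMIs in the 10 highest cells, while Il13 was 67.7 and 75.7 (0.895-fold [0.839 to 0.955]), Il5 1.32-fold [1.03 to 1.7002] and Gata3 347 and 292 (1.19-fold [1.15 to 1.22]). The list median was 0.04, with Il4 the only type 2 gene past 1.5-fold. With the drug, the type 2 share was 8.67% [7.63 to 9.81] and 6.70% [5.93 to 7.55] without it, 1.97 points [0.652 to 3.33] apart. Il17a was 34.6 and 15.4 CPM (2.25-fold [2.00 to 2.53]), Il17f 13.7 and 2.42 (5.64-fold [4.34 to 7.41]) and Il22 31.2 and 15.8 (1.98-fold [1.76 to 2.23]), with 27.9%, 50.9% and 62.2% of their UMIs in the 10 highest cells of WT rosiglitazone. Il17re and Il1r1 were also past 1.5-fold, Ccr6 was at 0.791-fold, and the median was 0.27. For the type 17 share the values were 5.04% [4.23 to 5.94] and 2.94% [2.43 to 3.53], 2.10 points [1.13 to 3.12] apart.

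Ifng was 29.5 CPM with the drug and 48.0 without (0.614-fold [0.560 to 0.673]), but the 10 highest cells held 55.8% of its UMIs in WT control, and the share of cells with an Ifng UMI was 2.58% and 2.81%, −0.233 points [−1.02 to 0.597]. The type 1 median was −0.02. Proliferation genes had a median of −0.34 (percentile 0), with Ccnb1 (16.1 and 27.0 CPM), Birc5 and Mki67 lower, Mki67 (132 and 184) by less than 1.5-fold. Cenpe, Wee1 and Tpx2 were also among the farthest lower genes. Naive or central memory genes had a median of 0.25, with the quiescence factor gene Klf2 (528 and 389 CPM) and Satb1 (1.36-fold) higher but within 1.5-fold. Interferon response (0.25, Ifit1 past 1.5-fold), tissue residency (0.18), stress (0.13), tissue repair (0.12), alpha-beta T cell (0.12) and T cell receptor activation (0.08) leaned higher. Zfp36, which encodes an mRNA decay factor, was 425 and 247 CPM, the chemokine receptor gene Cxcr4 196 and 125, Nr4a1 322 and 211, Rnaset2a 26.7 and 14.2 and Lgals7 379 and 238. In the PPARγ and lipid handling list (−0.04) the lipid droplet genes Hilpda (439 and 315 CPM) and Plin2 (38.9 and 33.2) were higher and Fabp5 (213 and 262) lower, none past 1.5-fold. Foxp3 was 255 and 268 CPM. Hdc, a histamine synthesis gene of the neutrophil list, was 28.0 and 15.3 CPM. Without thinning the difference in type 2 share was 6.05 points, and with thinning to 4000 UMIs 5.02 points.

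TKO rosiglitazone against TKO control asks what differs with the drug in mice labelled as T cell knockouts, whose deletion could not be checked here. The type 17 cytokine genes Il17a and Il17f, and Ifng, were lower with the drug. The regulatory T cell list leaned slightly higher, with no member past 1.5-fold. Il17f was 40.9 and 94.6 CPM (0.432-fold [0.397 to 0.470]) and Il17a 91.4 and 195 (0.468-fold [0.442 to 0.495]), whereas Il22 was 59.0 and 51.6 (1.14-fold [1.05 to 1.25]). Il17re (9.11 and 16.2 CPM) and the water channel gene Aqp3 were also lower, Tmem176b (0.722-fold) was between, and the list median was −0.41 (percentile 0). With the drug, the type 17 share was 12.7% [11.6 to 14.003] and without it 18.0% [16.6 to 19.6], a difference of −5.29 points [−7.20 to −3.39]. Type 1 genes had a median of −0.32, with Ifng at 25.3 and 59.1 CPM (0.428-fold [0.384 to 0.476]), and Xcl1 and Il12rb2 lower. Klrc1 (22.8 and 45.8 CPM), Klrk1 (70.9 and 114), Ifitm1 (159 and 307), Pxdc1 (80.0 and 126) and Adam8 (0.622-fold) were lower as well.

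Higher with the drug were Elovl6, a fatty acid elongase gene (35.8 and 20.6 CPM, 1.74-fold), Tnfrsf8, which encodes CD30 (43.6 and 28.2), Bmyc (126 and 82.5), Epcam (31.7 and 20.7) and the fatty acid-binding protein gene Fabp5 (290 and 210). Regulatory T cell genes had a median of 0.20 without any past 1.5-fold, Foxp3 was 280 and 237 CPM (1.18-fold [1.13 to 1.23]), and a Foxp3 UMI was found in 35.7% and 32.0% of cells. T cell receptor activation (−0.19), interferon response (−0.15, with Iigp1 at 11.4 and 18.9 CPM) and stress genes (−0.09) leaned lower; PPARγ and lipid handling (0.12), cytokine receptors and STAT signalling (0.11) and inhibitory receptors (0.11) leaned higher. In the type 2 list (0.10) Il5 was 12.7 and 9.74 CPM, Il4 9.06 and 11.7, Il13 83.8 and 96.0 and Il1rl1 308 and 248. The type 2 share was 6.203% and 4.63%, against the summed CPM (105.6 and 117.4), so no order is read. Hdc was 19.7 and 10.5 CPM. Under the stricter cell filter the type 17 share differed by −1.19 points [−3.61 to 1.15] between TKO rosiglitazone and TKO control, an interval that includes 0. T cells then numbered 2117 and 1254, beside 3440 and 2864 in the main filter. The 5% mitochondrial limit of that filter lay close to the median of the type 17-like cluster, 4.95%.

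TKO rosiglitazone against WT rosiglitazone asks whether the knockout difference persists under the drug. Type 17 genes were again higher in the knockout, by less than without the drug. Il4 was lower. As lists, type 1, interferon and naive genes leaned lower, while STAT, NF-kappaB and tissue repair genes leaned higher. Il17f was 40.9 and 13.7 CPM (2.99-fold [2.63 to 3.41]), Il17a 91.4 and 34.6 (2.64-fold [2.43 to 2.87]) and Il22 59.0 and 31.2 (1.89-fold [1.72 to 2.08]). Of 12 type 17 genes 11 were past 1.5-fold, with Tmem176a (77.5 and 36.5 CPM) and Tmem176b (67.5 and 32.6) among them and Aqp3 between, and the median was 1.00 (percentile 100). The type 17 share was 12.7% [11.6 to 14.003] and 5.04% [4.23 to 5.94], 7.71 points [6.24 to 9.18] apart. Il4 was 9.06 and 34.1 CPM (0.266-fold [0.224 to 0.313]), Gata3 291 and 347, Il13 83.8 and 67.7 (1.24-fold [1.15 to 1.33]) and Il5 12.7 and 5.62 (2.27-fold [1.83 to 2.82], over 78% of the UMIs of each library in 10 cells), with a type 2 median of −0.03. For Il13, the 10 highest cells held 51.9% of UMIs in TKO rosiglitazone and 35.1% in WT rosiglitazone. A single TKO rosiglitazone cell held 358 of 1638 Il13 UMIs, so the Il13 order may rest on it. The type 2 share was 6.203% [5.36 to 7.14] and 8.67% [7.63 to 9.81], −2.47 points [−3.87 to −1.10].

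Pxdc1 (80.0 and 30.3 CPM), Sgip1 (63.9 and 24.4), Dgat2 (63.9 and 28.3, 2.26-fold), Nmrk1 (101 and 48.8) and the autophagy gene Atg7 (41.1 and 20.6) were higher in the knockout. Stat5a (189 and 98.8 CPM) and Stat3 (523 and 341), whose product relays IL-6 and IL-23 signals, were the STAT genes past 1.5-fold in a list with a median of 0.31. NF-kappaB genes had a median of 0.38, with Tnf at 32.2 and 19.7 CPM, tissue repair genes 0.35, with Furin at 421 and 282, and glycolysis genes 0.16. Regulatory T cell genes had a median of 0.24, with Ikzf4 (110 and 60.4 CPM) and the IL-2 receptor gene Il2ra (539 and 348) past 1.5-fold. Lgals7 (104 and 379 CPM, 0.274-fold), Ifitm3 (105 and 295), Ifitm1 (159 and 421), Cd7 (46.1 and 87.4), Myo6 (16.8 and 31.5) and Rell1 (20.7 and 38.4) were the farthest lower beside Il4. Type 1 genes had a median of −0.35, with Nkg7 at 83.9 and 126 CPM, interferon response −0.29, naive −0.33, with Dapl1 lower but Ccr7 at 140 and 86.2, and alpha-beta T cell −0.26. CD8 list genes (−0.81) were lower, with Gzma at 19.6 and 41.8 CPM and Ctsw at 29.1 and 51.7, while Igkc of the B cell list (150 and 79.5) and Kit (13.5 and 7.62) were higher. The PPARγ and lipid handling median was 0.13 and the stress median 0.02. Without thinning the type 2 share differed by −7.09 points between TKO rosiglitazone and WT rosiglitazone, and the presence of Cre differs here too.

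**Figure D3:**
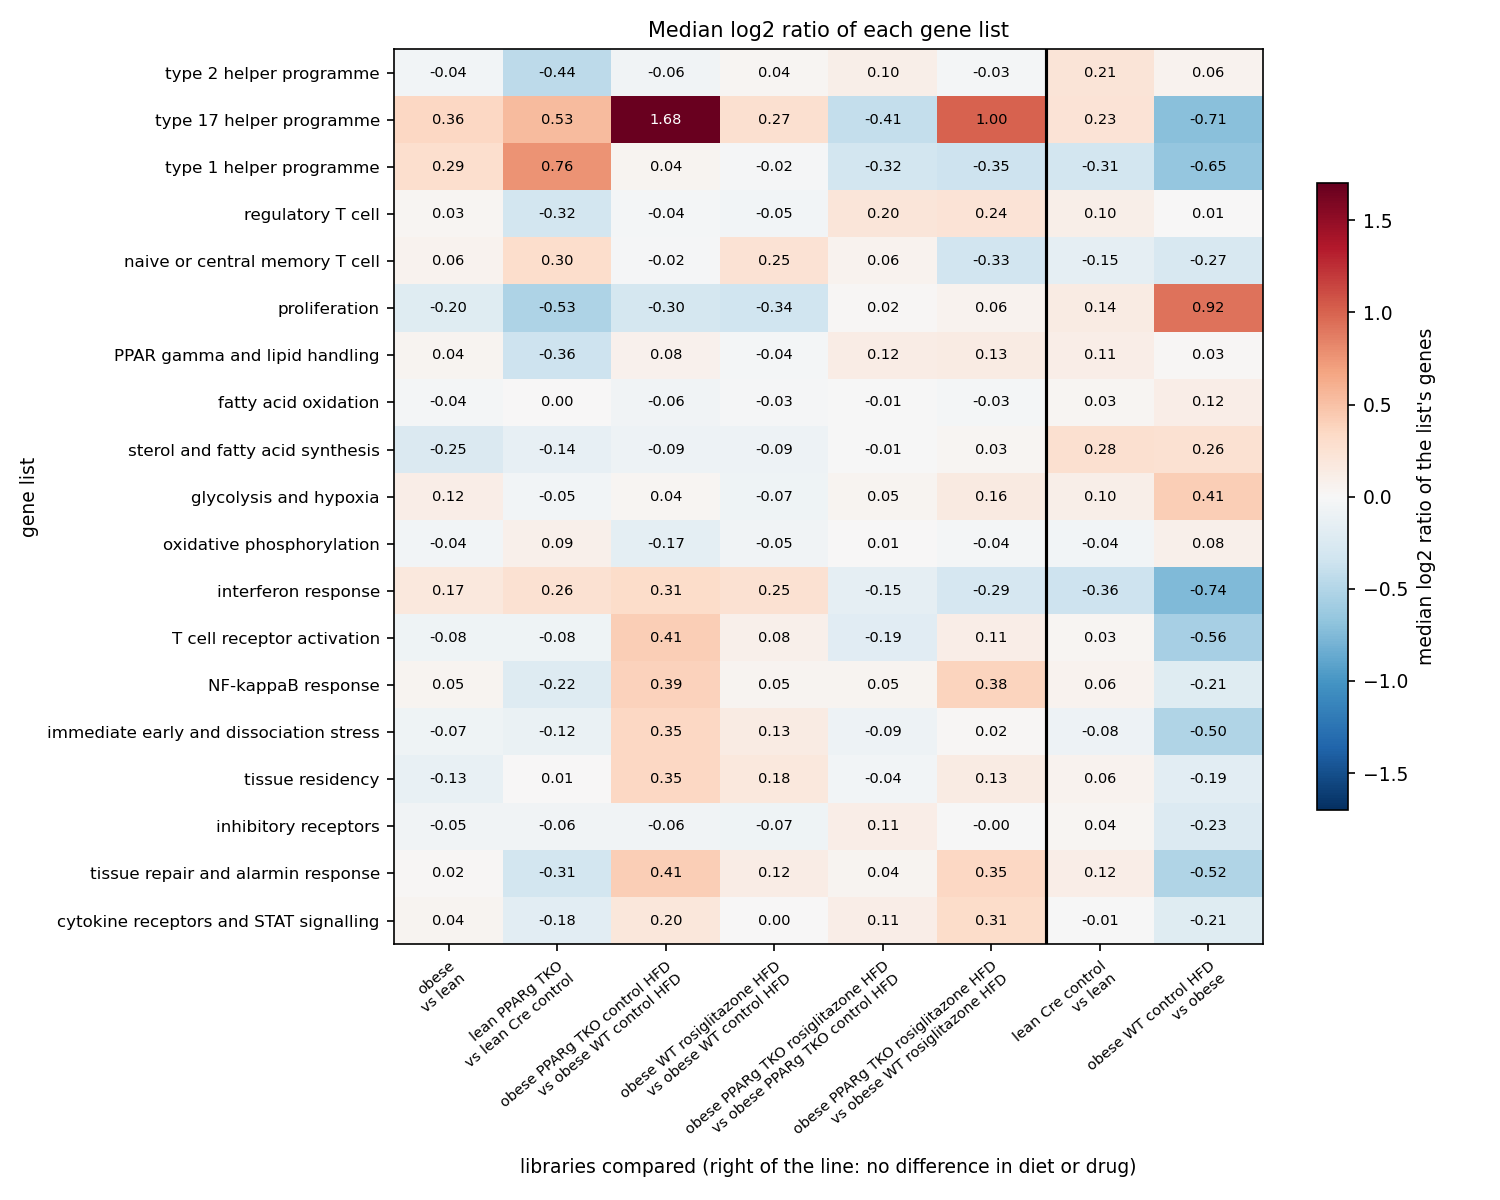
Median log2 ratio of gene lists (vertical axis) in the comparisons and in the contrasts with no difference in diet or drug (horizontal axis). The type 17 helper median was 1.68 for TKO control against WT control and −0.71 for WT control against obese.

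Do comparisons that share no library move the same genes? Over 5194 genes, which are not independent replicates, 14 correlations of log2 ratios were computed. The knockout difference without the drug and with it went together (Pearson 0.476, Spearman 0.404), and of 39 genes past 1.5-fold in both, 35 (89.7%) had the same direction, with Il17a, Il17f, Tmem176a and Rell1 among the genes named above. In both, the presence of Cre differs beside Pparg, so this does not tell the knockout from Cre or from other differences between the mice. The lean knockout comparison, with Cre in both libraries, did not go with the obese one (−0.0157). The drug in WT and in TKO mice had a negative value (−0.258). WT control against obese, with no drug in either library, had as large a value with the drug in TKO, 0.258. WT control is the reference in the former and the numerator in the latter, so the negative value may come from that library. Obese against lean had 0.143 with the lean knockout, 0.247 with the obese knockout and 0.0419 with the drug in WT. Correlations with the contrasts lacking a diet or drug difference ranged from −0.150 (WT control against obese, with the lean knockout) to 0.258 (WT control against obese, with the drug in TKO), and lean Cre control against lean had 0.163, −0.0795, −0.0690 and 0.176 with the obese knockout, the drug in WT, the drug in TKO and the knockout under the drug. WT control against obese had 0.0663 with the knockout under the drug, and both such contrasts 0.167 with each other.

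Markers of most other cell types were low in the T cells kept, whereas the B cell and dendritic cell lists, carried by Ighm, Igkc and Cd74, were about as high as Foxp3. Summed CPM were 112, 119, 69.5, 124, 84.1, 77.6, 109 and 61.2 for the CD8 list, 15.6, 17.8, 11.7, 23.8, 11.4, 21.6, 20.7 and 19.4 for gamma-delta T cells, 5.32, 5.74, 2.21, 2.48, 3.81, 5.42, 5.87 and 2.40 for natural killer or innate lymphoid cells (Fcer1g), and 378, 340, 386, 346, 335, 333, 287 and 350 for B cells (Ighm, Igkc). Macrophage genes (Cd68) summed to 7.99, 9.74, 12.4, 10.6, 8.20, 7.58, 9.99 and 9.52, dendritic cell genes (Cd74, which activated T cells can also express) to 244, 233, 204, 167, 245, 270, 262 and 286, neutrophil genes (Hdc) to 16.5, 16.3, 11.5, 14.9, 16.1, 11.4, 28.9 and 20.7, and mast cell or basophil genes (Kit) to 9.96, 10.3, 12.6, 14.2, 8.79, 19.3, 12.2 and 14.99. Keratinocyte genes (Sfn) summed to 38.2, 34.3, 45.0, 32.7, 42.8, 46.8, 42.3 and 48.5, fibroblast genes (Col1a1) to 2.66, 2.87, 2.51, 1.09, 2.87, 3.37, 3.91 and 5.22, and endothelial genes (Pecam1) to 42.1, 49.3, 47.8, 50.1, 41.2, 52.9, 41.1 and 54.4. Melanocyte genes (Pmel) were highest in WT control (3.67 CPM) and red blood cell genes (Hba-a1) in lean (4.11), and adipocyte genes (Retn) were at most 0.532 CPM. Follicular helper genes (Sh2d1a) summed to 138, 146, 118, 148, 114, 111, 122 and 118. Xist was found in at most 1 UMI per library and the Y-linked gene Ddx3y in every library.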

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

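Except for the share of Il17a cells with gamma-delta markers and the share of Il17a UMIs in the highest cells, every test below was chosen only after the result was seen.

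Rosiglitazone went with opposite directions in WT and TKO mice for part of the helper genes, in the order WT then TKO. The type 17 share differed by 2.10 and −5.29 points, the type 17 list median was 0.27 and −0.41, Il17a had log2 ratios of 1.12 and −1.09 and Il17f of 2.10 and −1.19. Under the stricter filter the TKO side shrank to −1.19 points [−3.61 to 1.15] in share, an interval that includes 0, and −0.18 in list median. Interferon response medians were 0.25 and −0.15, T cell receptor activation 0.081 and −0.19, stress genes such as Zfp36 0.13 and −0.089, and alpha-beta T cell genes 0.12 and −0.075. The knockout likewise differed in direction between lean and obese mice, in that order: NF-kappaB response −0.22 and 0.39, stress −0.12 and 0.35, tissue repair and alarmin response −0.31 and 0.41, cytokine receptors and STAT signalling −0.18 and 0.20, and Il5 −1.21 and 1.03. These opposite directions were not tested, since each rests on 4 single libraries. All of them use WT control as a reference, and its type 17 share was itself at −1.73 points against obese.

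Clusters left out as other cell types held 206 cells led by the chemokine gene Ccl3, 166 led by the antigen presentation gene H2-Aa, 61 led by the matrix gene Dcn and 50 led by Krt14 of basal keratinocytes. The hemoglobin gene Hba-a1 had 3065 UMIs outside the T cells in WT control and 2079 in WT rosiglitazone. It had 0 in TKO control and in TKO rosiglitazone, and at most 2 in each of the first 4 libraries. Among the last 4 libraries this difference coincides with genotype. Its cause was not tested, and the cells left out were not compared between groups.

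Type 17 genes were higher in TKO control than in WT control across cytokines and surface genes. A few very active cells cannot account for Il17a, because the 10 highest cells held 16.1% of its UMIs, but for Il22 they held 53.9%, so its ratio may rest on them. The barcodes of clusters 0 and 7 may add to the difference but are not its whole cause, since 11.9 of 15.1 points remained without them. Barcodes holding several T cells may also lie in other clusters, so leaving these 2 out cannot exclude them. Among other T cells, 2.42% in TKO control and 1.66% in WT control held both Foxp3 and helper cytokine UMIs. Gamma-delta T cells in the sort are left open: 19.8% [16.4 to 23.7] of TKO control cells with an Il17a UMI carried a gamma-delta list UMI. This lies around the 20% below which they were to be excluded, and 6.68% of those without Il17a did. Only 2.27% [1.14 to 4.03] of the Il17a cells carried Trdc, beside 0.966% of those without Il17a. In WT rosiglitazone 20.2% of Il17a cells carried a list UMI, at a type 17 share of 5.04%. The list is led by 5830411N06Rik (8.16 of 21.6 CPM in TKO control), itself a leading gene of the type 17-like cluster, so it is not independent of that programme. Loss of PPARγ, the presence of Cre, and chance between single libraries could each produce the same pattern, and the libraries cannot separate them.

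Clusters 0 and 7 held Foxp3 and helper cytokine UMIs in the same barcodes. Barcodes there with both made up 1.37 to 5.13 times the assumed rate of chance capture in the last 4 libraries, so random loading is left open. This test took the place of an earlier form after the values of both had been seen: counting every barcode of these clusters, the ratio was 7.15 to 13.6, past the 3 set as its bound, but only 19.2% to 37.8% of those barcodes held both kinds of UMI. Both Trbc1 and Trbc2, of which a T cell normally uses a single gene, were found 20.3 points more often than in clusters 3 and 10, which is consistent with barcodes that hold several T cells. The measure is far from specific, since 53.0% of barcodes in clusters 3 and 10 carried both genes, beside 73.3% in clusters 0 and 7 and 68.7% of simulated pairs. By the rule set, single cells rich in RNA are less likely, because the excess over cluster 10, also deep, was 23.3 points. Cluster 10 is shallower, though, at median 7291 UMIs against 8449 in cluster 0 and 12443 in cluster 7. Cluster 0 had both genes in 76.0% of barcodes. Cluster 7, part of the proliferating class, had them in 67.2%, below the simulated pairs, so for it the question stays open.

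Obese had the higher type 17 share beside lean. Diet may be the cause, but the spread between libraries of lean mice could be enough, as lean Cre control exceeded lean by 2.30 points. The difference may also depend on which cells the filter keeps, as it was 0.836 points under the stricter filter. That filter is not neutral here, because the type 17-like cluster had a median of 4.95% mitochondrial UMIs, close to its 5% limit. T cells then numbered 1541 in lean and 1747 in obese, beside 2265 and 3380 in the main filter. At the 20% limit all 12 cytokine share differences stayed within their counting intervals. Il22, Il17a and Il17f were all higher in obese, yet the same genes were higher in lean Cre control than in lean.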

How the results depend on the processing

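Of the alternatives below, leaving out clusters 0 and 7, the 20% mitochondrial limit, removal of the highest doublet scores and clustering of thinned cells were chosen only after the result was seen. No paired analysis was made, because every group has 1 library and no replicate, and the knockout pairs differ in diet, drug or presence of Cre. Differences in share are in percentage points, list values are medians, and the cause of each difference from the values above was not tested. Thinned to 4000 UMIs, the type 2 share differed by 0.571 (obese to lean), −3.52 (TKO control to WT control), 5.02 (WT rosiglitazone to WT control) and −7.67 (TKO to WT rosiglitazone), and the type 17 share by 22.7 (TKO control to WT control) and 13.2 (TKO to WT rosiglitazone). With no thinning, the type 2 share differed by −3.45 (lean TKO to lean Cre control), 6.05 (WT rosiglitazone to WT control) and −7.09 (TKO to WT rosiglitazone), and the type 17 share by 19.7, 3.53 and 9.58 for TKO control to WT control and those same drug comparisons. Without regulatory T cell-like clusters, the type 2 share differed by −3.53 (obese to lean) and −4.07 (lean knockout), the type 17 share by 3.24 (obese to lean), 20.5 (TKO control to WT control), −7.77 (drug in TKO) and 10.1 (TKO to WT rosiglitazone), and the type 2 list was −0.57 (lean knockout). Under the stricter filter, the type 17 share differed by 0.836 (obese to lean), 10.6 (TKO control to WT control) and −1.19 (drug in TKO), the type 2 share by 0.0480 (drug in TKO) and −3.88 (TKO to WT rosiglitazone), the type 2 list was −0.33 (lean knockout) and −0.13 (TKO control to WT control), and the type 17 list 1.47 (TKO control to WT control) and −0.18 (drug in TKO). Without clusters 0 and 7, the type 17 share differed by 11.9 (TKO control to WT control) and 5.76 (TKO to WT rosiglitazone), the type 2 share by 3.25 (drug in TKO), the type 17 list was 0.69 (lean knockout) and the type 2 list 0.14 (TKO to WT rosiglitazone). Without the highest doublet scores, the type 17 list was 0.65 (lean knockout) and 1.59 (TKO control to WT control); as a mean over cells, 0.82 and 1.48 for the same comparisons; with a pseudocount of 5 CPM, 1.43 (TKO control to WT control) and 0.85 (TKO to WT rosiglitazone). With the helper lists kept in clustering, the type 17-like share differed by 1.97, 3.04, 14.4, −1.35, −2.80 and 13.0 for obese to lean, lean knockout, TKO control to WT control, drug in WT, drug in TKO and TKO to WT rosiglitazone, and the type 1-like share by 5.14, 7.88, −2.00, −2.57 and −7.11 for obese to lean, lean knockout, TKO control to WT control, drug in TKO and TKO to WT rosiglitazone. With thinned cells clustered, the type 1-like share differed by 3.63 (obese to lean), 2.68 (lean knockout), 0.414 (TKO control to WT control, in the other direction from −0.980) and −3.02 (TKO to WT rosiglitazone), the type 17-like share by 20.3 (TKO control to WT control), 2.86 (drug in WT), −2.18 (drug in TKO) and 15.3 (TKO to WT rosiglitazone), and the proliferation-like share by −6.48 (TKO control to WT control) and −7.39 (drug in WT). Over all alternatives the sign was the opposite of the main value in 7 of 48 class share differences, 1 of 120 cytokine share differences and 7 of 144 list medians, and in 19 of 1332 values of single genes. Of the gene values, 189 of 666 left their counting interval as a mean over cells and 86 of 666 with median-of-ratios size factors. Further opposite signs among the values above are the type 17-like share for obese to lean with the helper lists kept (main −0.257) and for drug in WT with thinned cells clustered (main −0.136), the type 2 share for obese to lean at 4000 UMIs (main −1.33), and the type 2 list for TKO to WT rosiglitazone without clusters 0 and 7 (main −0.03). At resolution 0.5 no cluster took the type 1-like name, so that share has no value there. With thinned cells clustered, a cluster led by Myo6 and Pdlim4, like the unnamed cluster 6 above, took the naive-like name. Some clusters there with most markers from the regulatory T cell list took no name. The naive-like and regulatory T cell-like classes therefore cover other cells in that clustering.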

Other observations

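Of the genes with a mean of at least 20 CPM, 5 lay past 1.5-fold in the same direction in all 3 knockout comparisons (lean, obese, obese with rosiglitazone), and 13 lay past it in all 3 regardless of direction; this was chosen after the values were seen. Tmem176a (log2 ratios 0.74, 1.77 and 1.06), Tmem176b (0.62, 1.71 and 1.03), ion channel genes tied to type 17 cells, and the protease inhibitor gene Serpinb1a (0.68, 0.99 and 0.80) were higher. Rell1, a TNF receptor family relative (−1.53, −1.01 and −0.86), and Myo6, which encodes an unconventional myosin (−0.96, −1.42 and −0.87), were lower. Rell1 hardly differed elsewhere: 0.04 for obese against lean, −0.13 and 0.02 for the drug in WT and TKO mice, 0.06 for lean Cre control against lean and −0.10 for WT control against obese. Myo6 was not so quiet, with 0.71 for obese against lean, 0.68 for the drug in TKO mice and 0.53 for lean Cre control against lean.

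Within the type 17-like cluster, Il13 was lower in knockout cells without the drug, a result also chosen after its values were seen. It was 6.48 CPM in lean TKO and 121 in lean Cre control (0.0536-fold [0.0170 to 0.130], 5 and 94 UMIs), and 20.8 in TKO control and 155 in WT control (0.134-fold [0.0910 to 0.193], 38 and 137 UMIs). A type 2 cytokine UMI was found there in 2.45% [0.673 to 6.16] of lean TKO and 11.7% [6.71 to 18.6] of lean Cre control cells, and in 3.02% [1.57 to 5.22] and 13.6% [8.94 to 19.6] of TKO and WT control cells. Without thinning, which had left 176 of 379 WT control cells, the shares were 5.29% and 27.3% in lean and 5.64% and 11.3% in obese mice. In cluster 3 Il13 was instead higher in both knockouts, 662 against 524 CPM in lean and 328 against 250.0 in obese mice, as it was over all T cells. Under rosiglitazone Il13 in the type 17-like cluster was not lower in the knockout, with 107 CPM in TKO and 81.9 in WT (1.31-fold [0.944 to 1.83]). Il17a in the same cluster was 534 CPM in TKO control and 10.2 in WT control (52.4-fold [27.5 to 115]), and the type 17 cytokine share there was 42.3% and 10.2%; under rosiglitazone Il17a was 233 and 198 CPM (1.17-fold [0.951 to 1.45]).

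The content of the cluster differs by library: Il17a was 12.5 CPM in lean, with Ifng at 258, and 10.2 in WT control, below the 15.4 of all T cells of that library. These ratios are therefore not read as differences within a fixed kind of cell, and no mechanism is read from them, since the deletion could not be checked. Rell1 leaves an open question, whether it is a direct PPARγ target in T cells, which binding data for the receptor would answer.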
